A study of Caenorhabditis elegans with 12 samples.

How the data were processed

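RNA of young adult hermaphrodite Caenorhabditis elegans of the N2 strain was measured on 12 Affymetrix arrays, 1 labelled sample per array, in 4 groups of 3. Per the labels' protocols, L1 larvae were fed for 48 hours at 20 C either bacteria with the empty RNAi vector L4440 (control RNAi) or bacteria carrying the zip-2 RNAi clone. They were then moved for 4 hours to plates with Escherichia coli OP50 (uninfected) or Pseudomonas aeruginosa PA14 (infected). The infection effect is the difference between these bacteria, so infection and a change of bacterial food cannot be told apart. Groups and replicate numbers came from the sample titles. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

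The deposited values are signal intensities on a linear scale, 1 per probe set and array, per the file headers. A second deposited table gives a Present, Marginal or Absent call per probe set and array, per the file headers. Their software and version are not given in the sources used here. The 2% trimmed mean of every array lay between 500.1 and 500.2, so that the deposited signal intensities had been scaled per array. Array medians lay between 81.4 and 110.1, a ratio of 1.35, and the arrays were therefore used as deposited, without further normalization. The share of Present calls per array ran from 53.25% to 58.54%. The columns of the second table name the group but not the replicate number, so its calls were used per group, and 24 of its columns were not used. They also carry a letter, G, H or I. Each letter occurs in all 4 groups, and no label says what it stands for. No pair of arrays held identical values, and the number of arrays limits the precision.

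Of 22625 probe sets, 77 control probe sets were left out. Probe sets with a Present call on fewer than 3 of the 12 arrays (8864) were not tested, which left 13684. Gene names came from the platform's annotation table. Of the probe sets other than controls, 20766 had 1 gene name, 887 had several and 895 had none, and only those with 1 name are named. Symbols were updated through the gene ID with a RefSeq gene table (assembly WBcel235) for 20701 of them, and that table was used for names and gene order only. Chromosomes came from the probe set descriptions in the deposited table. A gene was represented by its probe set with the highest mean, which gave 10357 genes.

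All values were taken as log2(signal + 16), which understates the change of genes with low signal. One linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend = TRUE) in R 4.3.3, leaving 8 residual degrees of freedom. It gave 5 contrasts: the infection effect in each RNAi group, the effect of zip-2 RNAi on each bacterium, and the difference of the infection effects between the RNAi groups. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over the 13684 probe sets, and a probe set was called at an adjusted p under 0.05. Every ± beside a log2 change is the standard error from this model, and every ± beside a signal is the SD of 3 arrays. An exact permutation test of 3 against 3 cannot go below 0.1, so only the limma p is given per gene. Where a group had no Present call for a gene, or for a called change 1 Present call and a mean under the floor, the change is a bound, written "at least N-fold". It sets the mean log2(signal + 16) of the detected group against that of, per array, the higher of the gene's own signal and a floor. Where the gene's own signal is the higher on all 3 arrays, the bound equals the fitted fold. The bound concerns detection only and allows for no sampling error. The floor is the array's lowest signal among probe sets called Present on all 3 arrays of its group.

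The genes named were chosen by a rule. It takes zip-2, all irg genes and the 10 largest rises and 10 largest falls of each contrast among calls in which all 3 values of one group lay beyond all 3 of the other. It also takes up to 4 members of each gene list with the largest moderated statistic. For the difference of infection effects the condition on the 3 values was left out. The 24 gene lists were irg genes, PMK-1 targets, CUB-like genes, C-type lectins, lysozymes, caenacins and nlp peptides, saposin-like and antibacterial factor genes, the intracellular pathogen response, cytochromes P450, glucuronosyltransferases, glutathione S-transferases, SKN-1 targets, DAF-16 targets, cytosolic heat shock genes, ER and mitochondrial unfolded protein response genes, metal response genes, bZIP factors, aspartyl and cathepsin B-like proteases, fatty acid metabolism, ribosomal proteins, collagens, vitellogenins and major sperm proteins. Markers of 7 tissues (oocyte and embryo, germline, intestine, epidermis, body wall muscle, pharynx and neuron) made up 31 lists tested. Lists, tests, the naming rule and most alternatives were fixed before the data were examined. Each list was tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 31 lists. Counts of members use the adjustment over all probe sets, followed by the count adjusted over the list alone. Lists called by camera are given with the adjusted p of camera with an estimated correlation as well, and for lists not called it is left out.

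The mean log2 3'/5' ratio of 4 control transcripts was 0.62 in uninfected and 0.68 in infected control RNAi arrays, and 0.57 and 0.77 in zip-2 RNAi arrays. Infection thus came with a rise of 0.06 ± 0.04 in control RNAi and of 0.19 ± 0.04 in zip-2 RNAi. A fit with this ratio as a covariate was therefore added after the data were seen. Because the ratio follows infection in zip-2 RNAi, that fit has larger standard errors, and a call lost in it is left open rather than assigned to RNA quality.

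The groups share replicate numbers 1 to 3, which come from the titles. Pairing was checked by correlating, across probe sets, the deviations of same-numbered arrays from their group means. For zip-2 RNAi against control RNAi in uninfected animals the correlations were 0.12, 0.17 and 0.25, and for infection in zip-2 RNAi they were 0.31, 0.35 and 0.17. For infection in control RNAi they were 0.37, 0.09 and 0.41, and for zip-2 RNAi in infected animals 0.03, 0.14 and 0.09. All 12 arrays had their best correlation with an array of another group at their own number. The numbers may therefore pair the arrays, and the letters in the second table's columns may mark sets of arrays too. No label ties the letters to the numbers. The fit reported has no block, so its counts and p-values are unpaired, and a fit with the replicate number as a block is given beside main results that it changed.

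The alternatives were the replicate block, no detection filter or a stricter one (12636 probe sets), an offset of 1 or 64, quantile normalization, centring on the 75th percentile, eBayes without trend, only the groups compared, array weights, fry and all probe sets of a list, and leaving out each array in turn. Changes of fold 1.5, 2, 4 and 8 were tested on simulated data, with 50 probe sets per size among the 13684. The changed probe sets were drawn only from those with a higher mean signal, and the noise was independent between probe sets and arrays. The shares called therefore do not hold for genes near the floor or for samples that vary together. For infection in control RNAi 52%, 92%, 98% and 100% of them were called, for zip-2 RNAi in infected animals 56%, 90%, 98% and 100%, and for the difference of infection effects 36%, 78%, 92% and 98%. Of 20 random lists of unchanged genes in these simulated data, 0 were called by camera. Genes varied independently there, so this does not test whether the preset correlation is high enough for the real arrays. No sample was left out.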

Results

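Transcripts of young adult C. elegans were measured on 12 arrays in a design that crossed RNAi (empty vector or zip-2) with bacterium (E. coli OP50 or the pathogen P. aeruginosa PA14, for 4 hours), with 3 arrays in each of the 4 groups. The question, from the series title, was which genes are regulated by zip-2, which encodes a bZIP transcription factor, with and without infection. Signals are linear intensities scaled per array, with medians between 81.4 and 110.1. Infection here means PA14 in place of OP50, so effects of the pathogen and of the change of food cannot be told apart.

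The zip-2 transcript itself (K02F3.4, chromosome 3) was lower in zip-2 RNAi on both bacteria. In uninfected animals its signal was 970 ± 71.3 (SD, n = 3) with control RNAi and 200 ± 14 with zip-2 RNAi, a log2 change of -2.19 ± 0.12 or 4.55-fold (adjusted p = 7e-07). In infected animals it was 2840 ± 507 against 288 ± 14, a log2 change of -3.22 ± 0.12 or 9.3-fold (adjusted p = 4.5e-09). Infection raised zip-2 by 1.52 ± 0.12 (2.87-fold, adjusted p = 1.1e-06) in control RNAi and by 0.49 ± 0.12 (1.41-fold, adjusted p = 0.009) in zip-2 RNAi. The rise in zip-2 RNAi was not called with the mean 3'/5' ratio of control transcripts as a covariate (0.64 ± 0.26, adjusted p = 0.3). Whether the RNAi clone overlaps the zip-2 probes of the array was not known, so the signal in zip-2 RNAi is not known to come from the transcript of the animals alone.

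**Figure D1:**
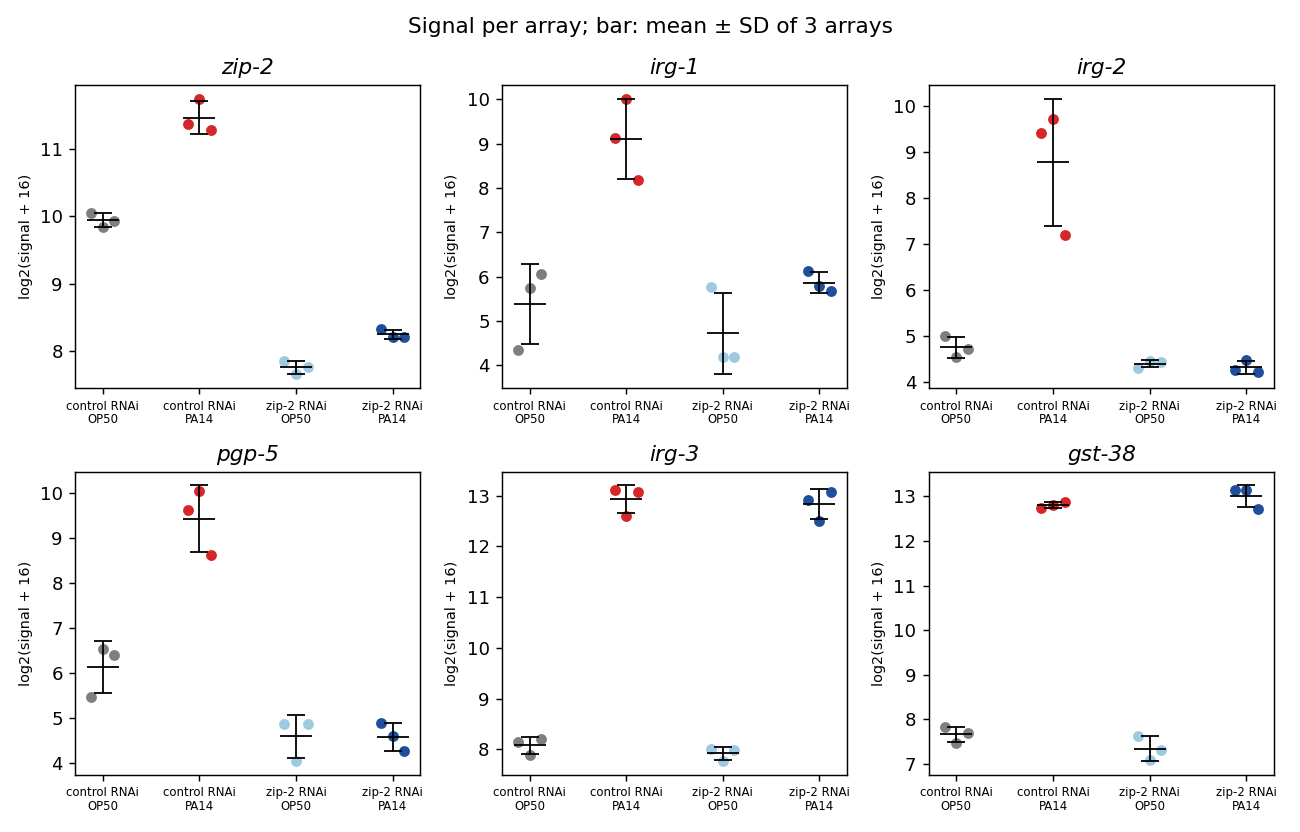
Signal per array of zip-2 and of 5 genes raised by infection in control animals, as log2(signal + 16), with 3 points per group and the mean ± SD. In infected zip-2 RNAi animals irg-2 has a mean signal of 4.1 and pgp-5 of 8.33, while irg-3 has 7390 and gst-38 has 8280.

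Among the largest rises with infection in control RNAi were gst-38, a glutathione S-transferase (5.14 ± 0.14, from 188 ± 24.2 to 7140 ± 366), irg-3 (4.85 ± 0.16), clc-19, a claudin-like gene (4.77 ± 0.17), the CUB-like gene F55G11.2 (4.71 ± 0.14), the noncoding RNA tts-1 (4.57 ± 0.34), C17H12.6 (4.54 ± 0.15) and irg-5 (4.40 ± 0.37). Genes with no Present call before infection were C50F7.5 (at least 29.6-fold higher), fbxc-58, an F-box gene (at least 22.2-fold), and C06B3.7 (at least 18.6-fold). Adjusted p for these 10 genes ran from 7.6e-11 for gst-38 to 3.3e-05 for fbxc-58. The largest fall was that of acdh-1, an acyl-CoA dehydrogenase (-5.0 ± 0.41, from 2950 ± 1860 to 62.1 ± 10.2, adjusted p = 2.2e-06). The beta-oxidation genes hacd-1 (-3.04 ± 0.25) and ech-7 (-2.93 ± 0.21), ttr-44 (-3.71 ± 0.27), the aspartyl protease gene asp-13 (-2.99 ± 0.28), pmp-5, a peroxisomal transporter gene (-2.79 ± 0.24), and sdz-24 (-2.73 ± 0.18) followed. Without a Present call after infection were ugt-17 (at least 7.14-fold lower), C45E5.1 (at least 6.71-fold) and the carboxylesterase gene cest-10 (at least 5.85-fold).

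In control RNAi 3 lists of defence genes were called higher also with an estimated correlation. These lists share members, so they are not 3 separate results. The gene irg-4 is in all 3, irg-5 is also a PMK-1 target and irg-6 also a CUB-like gene. Others, such as dod-22 and C17H12.8, are in both the PMK-1 and the CUB-like list. Of 8 irg (infection response) genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 3.88, or 3.80 with undetected genes at their bound (camera adjusted p = 6.9e-11, adjusted p = 0.0055 with an estimated correlation). Some irg genes were named by the laboratory that made these arrays, so this count is not independent evidence. The 6 were irg-1 (3.73 ± 0.52, adjusted p = 0.00022), irg-2 (at least 14.5-fold), irg-3, irg-4 (2.39 ± 0.30), irg-5 and irg-6 (at least 16.6-fold). Not called were irg-7 (0.35 ± 0.12, adjusted p = 0.084) and irg-8 (0.23 ± 0.10, adjusted p = 0.2), while with the replicate block 7 irg genes were called, irg-7 among them (adjusted p = 0.033). All 12 CUB-like genes rose (12 adjusted over the list alone), with a median of 2.53 (adjusted p = 6.4e-23 and, with an estimated correlation, adjusted p = 0.0055), among them dod-24 (2.87 ± 0.07), dod-17 (3.01 ± 0.19) and mbug-1 (4.32 ± 0.27). Of 10 targets of the p38 kinase PMK-1, 9 rose (9 adjusted over the list alone), with a median of 1.54 (adjusted p = 6.9e-11 and, with an estimated correlation, adjusted p = 0.047, or 0.13 with the replicate block besides), such as clec-67 (2.10 ± 0.14), clec-85 (1.44 ± 0.13) and C17H12.8 (1.28 ± 0.12).

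Other defence families changed in both directions and were not called as lists, except the intracellular pathogen response. Of 75 C-type lectins 19 rose, such as clec-174 (3.52 ± 0.27), clec-173 (2.42 ± 0.14) and clec-41 (2.32 ± 0.11), and 11 fell (20 and 13 adjusted over the list alone). Their median was -0.02, their mean 0.25 and the direction of the test up (adjusted p = 0.12). Of 10 lysozymes 3 rose, such as lys-8 (0.89 ± 0.12), and 2 fell, such as ilys-5 (-1.57 ± 0.14) (5 and 2 adjusted over the list alone; adjusted p = 0.49). Of 12 saposin-like and antibacterial factor genes 2 rose, spp-18 (1.62 ± 0.17) and spp-8 (1.25 ± 0.11), and 4 fell, such as spp-23 (-1.87 ± 0.27) (2 and 5 adjusted over the list alone; adjusted p = 0.45). Of 11 caenacins and nlp peptides 6 rose, such as nlp-28 (1.48 ± 0.24), and 1 fell (6 and 3 adjusted over the list alone; adjusted p = 0.12). Of 10 genes of the intracellular pathogen response 3 rose (3 adjusted over the list alone), skr-3 (1.39 ± 0.17), cul-6 (1.36 ± 0.29) and pals-23 (at least 3.48-fold), with a camera adjusted p = 0.0091 that was lost with an estimated correlation (adjusted p = 0.25) and without the detection filter (adjusted p = 0.2).

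Among stress and detoxification genes, 10 of 25 glutathione S-transferases rose and 3 fell (12 and 6 adjusted over the list alone), with gst-6 (2.47 ± 0.13) and gst-5 (2.08 ± 0.19) after gst-38. The list was called at the preset correlation (camera adjusted p = 0.0096, adjusted p = 0.66 with an estimated correlation, and adjusted p = 0.16 without infected control array number 3). Of 8 SKN-1 oxidative stress targets 4 rose, such as gcs-1, which makes glutathione (1.23 ± 0.08), and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0057 and, with an estimated correlation, adjusted p = 0.25). Of 16 ER unfolded protein response genes 5 rose, such as the chaperone gene hsp-4 (0.78 ± 0.07), and 1 fell, the translocon gene sec-61.A (-0.50 ± 0.08) (5 and 1 adjusted over the list alone; adjusted p = 0.0071 and, with an estimated correlation, adjusted p = 0.14). Of 17 bZIP factors 7 rose, among them zip-10 (1.69 ± 0.17), zip-5 (1.39 ± 0.13) and jun-1 (0.85 ± 0.12) besides zip-2, and 1 fell (10 and 2 adjusted over the list alone; adjusted p = 0.00014 and, with an estimated correlation, adjusted p = 0.15). Not called as lists were cytochromes P450 (9 of 38 higher and 6 lower, 9 and 8 adjusted over the list alone; adjusted p = 0.81). Neither were glucuronosyltransferases (10 of 45 higher, such as ugt-31 at 2.21 ± 0.26, and 14 lower, 13 and 18 adjusted over the list alone; adjusted p = 0.19). The same held for metal response genes (3 of 7 higher, such as cdr-1 at 1.61 ± 0.23, and 1 lower, mtl-2 at -1.31 ± 0.21, 4 and 3 adjusted over the list alone; adjusted p = 0.49). Also not called were DAF-16 targets (2 of 9 higher and 1 lower, 2 and 3 adjusted over the list alone; adjusted p = 0.92) and cytosolic heat shock genes (1 of 6 higher and 0 lower, 1 and 0 adjusted over the list alone; adjusted p = 0.95). Of 9 mitochondrial unfolded protein response genes 1 rose and 2 fell, among them hsp-60 (-0.56 ± 0.07) (1 and 3 adjusted over the list alone; adjusted p = 0.4).

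Of 57 genes of fatty acid metabolism 12 rose, such as the carnitine palmitoyltransferase gene cpt-4 (at least 6.64-fold), and 14 fell, such as the elongase genes elo-5 (-1.80 ± 0.16) and elo-2 (-1.59 ± 0.12) (14 and 16 adjusted over the list alone; adjusted p = 0.4). Of 16 aspartyl and cathepsin B-like proteases 5 rose, such as cpr-3 (2.78 ± 0.18), asp-12 (2.48 ± 0.22) and asp-14 (1.98 ± 0.14), and 8 fell (6 and 9 adjusted over the list alone; adjusted p = 0.49). Of 82 genes of the collagen list 13 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 7.8e-08, adjusted p = 0.49 with an estimated correlation). Those with the strongest statistic, dpy-18 (-1.22 ± 0.15) and dpy-11 (-0.51 ± 0.06), encode enzymes of collagen processing rather than collagens. Of 5 vitellogenins 1 fell, vit-1 (-1.01 ± 0.16) (4 adjusted over the list alone; adjusted p = 0.0061 and, with an estimated correlation, adjusted p = 0.53). The 74 ribosomal protein genes had a median of -0.17 (1 lower and 0 higher over all genes, 0 adjusted over the list alone; adjusted p = 1.5e-10 and, with an estimated correlation, adjusted p = 0.71), which became 0.01 (adjusted p = 0.65) with quantile normalization. That normalization also ended the vitellogenin call (adjusted p = 0.31).

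With infection in control RNAi, none of the 15 oocyte and embryo, 13 germline, 8 epidermis, 7 pharynx or 11 body wall muscle markers or of the 32 major sperm protein genes was called in either direction, over all genes or adjusted over the list alone (limma). At an unadjusted p under 0.05, 8 muscle markers, 2 germline markers, 1 pharynx marker and 1 sperm gene were lower, 1 germline marker was higher, and of the oocyte and epidermis markers 0 passed. The list adjusted p was 0.69, 0.94, 0.94, 0.81, 0.0051 and 0.24, in that order. The call of body wall muscle (median -0.29) was lost with an estimated correlation (adjusted p = 0.71) and with quantile normalization (adjusted p = 0.12). Of 12 intestine markers 4 rose, such as the peptide transporter gene pept-1 (0.76 ± 0.15), and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.49). Of 12 neuron markers 2 rose, unc-64 (0.96 ± 0.21) among them (2 adjusted over the list alone; adjusted p = 0.85).

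In this comparison limma called 1758 of 13684 probe sets, 935 higher (778 genes) and 823 lower (708 genes), of which 399 and 187 changed 2-fold or more. The balance of rises and falls rested on the scaling, with 828 higher and 1010 lower after centring on the 75th percentile and 889 and 887 after quantile normalization. For 27.7% of probe sets the 3 infected and 3 uninfected values did not overlap, where chance gives 10%. Of the 94 called genes named for this comparison, 85 stayed called whichever array was left out, and irg-7 became called (0.48) without uninfected control array number 3.

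In zip-2 RNAi the infection response was broad as well, with 2167 probe sets called, 1178 higher (971 genes) and 989 lower (826 genes), 487 and 254 of them 2-fold or more. Quantile normalization gave 1113 higher and 1141 lower. The largest rises were gst-38 (5.66 ± 0.14), F53B2.8 (5.36 ± 0.29), the lectin gene clec-3 (at least 26.9-fold), tts-1 (5.03 ± 0.34), C17H12.6 (5.02 ± 0.15), irg-3 (4.91 ± 0.16), F55G11.2 (4.84 ± 0.14), B0024.4 (4.66 ± 0.39), clc-19 (at least 24.5-fold) and C50F7.5 (at least 24.2-fold). The largest falls were acdh-1 (at least 44.7-fold), ttr-44 (-4.25 ± 0.27), the folate transporter gene folt-2 (-3.53 ± 0.44), ugt-17 (at least 10.5-fold), C45E5.1 (at least 8.01-fold), cest-10 (at least 7.22-fold), ifc-1, an intermediate filament gene (at least 6.35-fold), F46F2.3 (-3.27 ± 0.34), pmp-5 (-2.80 ± 0.24) and asp-13 (-2.77 ± 0.28). Adjusted p for these genes lay at or below 6.1e-05 (folt-2). With the 3'/5' ratio of control transcripts, which was higher after infection in zip-2 RNAi, as a covariate 454 probe sets were called, 444 of the 2167 among them, and 54 of the 100 genes named here. Standard errors were then larger by a median of 2.24 times, and 2149 of the 2167 changes kept their direction. The groups did not overlap for 30% of probe sets, where chance gives 10%, and 90 of the 100 called genes named here stayed called whichever array was left out.

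Of the 8 irg genes 6 were called higher in zip-2 RNAi as well (6 adjusted over the list alone; camera adjusted p = 3.2e-07 and, with an estimated correlation, adjusted p = 0.024). Their median was 1.54, or 1.93 with undetected genes at their bound or left out. These were irg-3, irg-6 (at least 18.5-fold), irg-5 (3.67 ± 0.37), irg-4 (1.93 ± 0.30), irg-7 (0.63 ± 0.12, adjusted p = 0.0022) and irg-8 (0.53 ± 0.10, adjusted p = 0.0023). With the 3'/5' covariate only irg-3 (5.17 ± 0.34) and irg-6 (adjusted p = 0.00064) of these stayed called. The other 4 kept a rise with larger standard errors, irg-5 3.27 ± 0.83, irg-4 1.76 ± 0.68, irg-8 0.75 ± 0.22 and irg-7 0.50 ± 0.27. Not called were irg-1 (1.15 ± 0.52 as fitted, adjusted p = 0.19) and irg-2, which had no Present call on either bacterium (adjusted p = 0.95). The signals of irg-1 before infection were 38.8, 2.3 and 2.1, so the size of its fitted change rests on the offset. The call of irg-1 depended on uninfected zip-2 RNAi array number 1, without which it rose by 1.68 (adjusted p = 0.045). All 12 CUB-like genes rose (12 adjusted over the list alone), with a median of 3.04 (adjusted p = 1.2e-22 and, with an estimated correlation, adjusted p = 0.0085). Of 10 PMK-1 targets 9 rose (9 adjusted over the list alone, which also calls 1 lower), with a median of 1.86 (adjusted p = 1.9e-10 and, with an estimated correlation, adjusted p = 0.051). Of 45 glucuronosyltransferases 18 fell and 2 rose (19 and 2 adjusted over the list alone; adjusted p = 3.6e-05 and, with an estimated correlation, adjusted p = 0.18). Of 82 collagen list genes 33 fell and 1 rose (41 and 1 adjusted over the list alone; adjusted p = 1.4e-09 and, with an estimated correlation, adjusted p = 0.3). The other lists called were bZIP factors (10 of 17 higher and 1 lower, 10 and 1 adjusted over the list alone, adjusted p = 4.7e-05 and, with an estimated correlation, 0.15), body wall muscle markers (3 of 11 lower, 5 adjusted over the list alone, adjusted p = 0.0022 and 0.49) and the intracellular pathogen response (5 of 10 higher, 5 adjusted over the list alone, adjusted p = 0.0049 and 0.21). Intestine markers (median 0.44, adjusted p = 0.007), C-type lectins (0.13, adjusted p = 0.011), lysozymes (0.64, adjusted p = 0.024), SKN-1 targets (0.46, adjusted p = 0.034) and ER unfolded protein response genes (0.15, adjusted p = 0.036) followed. With an estimated correlation these 5 were not called (adjusted p = 0.23, 0.52, 0.31, 0.31 and 0.21). Of these 5, all but the intestine markers lost the call without infected zip-2 RNAi array number 1 (adjusted p = 0.052 to 0.083), and SKN-1 targets also with the replicate block (adjusted p = 0.091). Intestine markers and ER unfolded protein response genes lost it with the 3'/5' covariate (adjusted p = 0.32 and 0.16). In all, 13 of 31 lists were called and 2 of them, irg and CUB-like genes, with an estimated correlation too.

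The infection effects in the RNAi groups, which share no array, had a Pearson correlation of 0.844 and a Spearman correlation of 0.61 across probe sets, which are not independent replicates. Called higher in both were 755 probe sets, where independent lists would share 80.5, and called lower in both were 634, where independent lists would share 59.5. These expected numbers do not allow for same-numbered arrays of the RNAi groups that deviate together. Their correlations were 0.12, 0.17 and 0.25 in uninfected and 0.03, 0.14 and 0.09 in infected animals. Of 334 genes raised 2-fold or more in control RNAi, 299 were also called higher in zip-2 RNAi. Their median rise was 1.60 in control RNAi and 1.64 in zip-2 RNAi (1.58 and 1.66 with undetected genes at their bound or left out). This gave a median difference of 0.10, and a range from -1.64 at the 5th to 0.77 at the 95th percentile. The difference of infection effects was called negative for 7 of these genes and positive for 0 (limma), of 52 and 47 at an unadjusted p under 0.05. The fold in zip-2 RNAi was under 50% of the control fold for 29 genes and over 2 times that fold for 11, in genes chosen for their rise in control RNAi. Both the 7 and the 29 include zip-2 itself, the RNAi target. With genes chosen without one replicate number and measured in the left-out one, the median difference was -0.08, 0.15 and 0.35 (mean 0.14, SD 0.22), a difference smaller than its spread. In these choices 21, 29 and 37 genes lay under 50% of the control fold and 3, 18 and 53 over 2 times that fold, so the balance of the 29 and 11 genes did not hold in every replicate number.

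**Figure D2:**
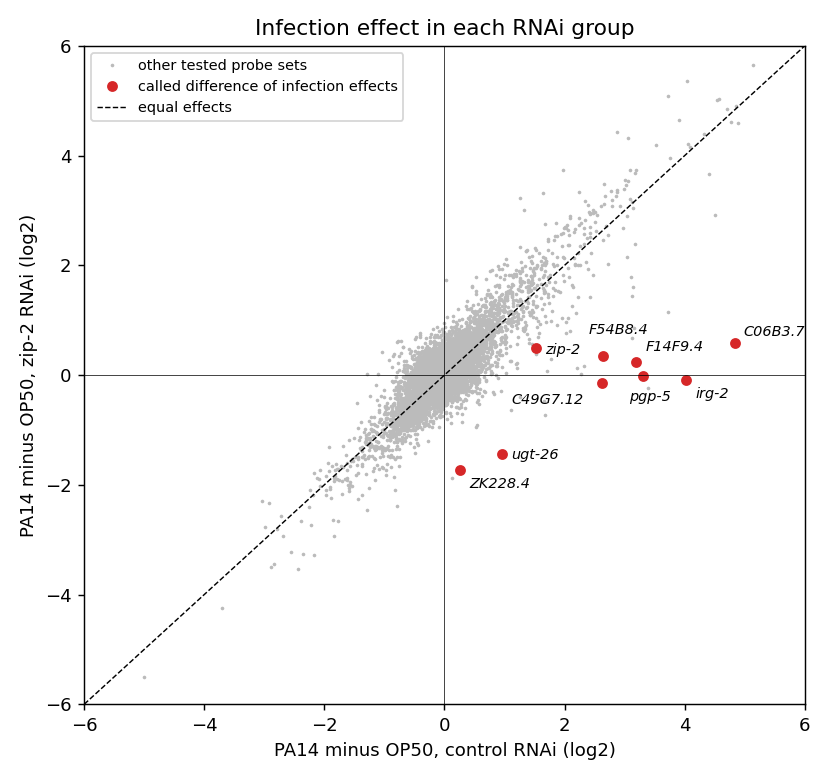
Infection effect (log2) per probe set in control RNAi on the x axis and in zip-2 RNAi on the y axis, with the 9 called differences in red. Most probe sets lie along the diagonal (Pearson 0.844 across probe sets), and the 9 lie below it, among them zip-2 with a difference of -1.03.

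In uninfected animals 8 genes besides zip-2 were called in the unpaired fit, each lower in zip-2 RNAi. With the replicate block many more probe sets were called, in both directions, as given below. The epoxide hydrolase gene ceeh-1, which lies next to zip-2 on chromosome 3, fell at least 6.07-fold, from 211 ± 25.4 to 20.9 ± 16 (adjusted p = 0.00097), with no Present call in zip-2 RNAi. The others were C25D7.2 (-1.57 ± 0.24), the lectin genes clec-47 (-1.38 ± 0.17) and clec-67 (-1.0 ± 0.14), Y37E11B.10 (-1.19 ± 0.16), gst-6 (-0.84 ± 0.13), F32H2.7 (-0.76 ± 0.12) and the CUB-like gene C17H12.8 (-0.73 ± 0.12, adjusted p = 0.048). None of the 8 irg genes was called by limma (1 lower adjusted over the list alone, 2 lower at an unadjusted p under 0.05), and irg-8 came closest (-0.44 ± 0.10, adjusted p = 0.074; adjusted p = 0.028 with the replicate block).

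In uninfected animals 15 of 31 lists were called for zip-2 RNAi at the preset correlation and 0 with an estimated one (adjusted p = 0.49 to 0.73). The oocyte-minus-sperm marker index was higher in zip-2 RNAi than in control RNAi arrays of both bacteria by 0.81 ± 0.19 (SE, with the 12 arrays taken as independent). Major sperm protein genes had a median of -0.57, with 0 of 32 called over all genes and 27 lower adjusted over the list alone (camera adjusted p = 1.9e-14, adjusted p = 0.49 with an estimated correlation). With the replicate block 24 were called lower (camera adjusted p = 3.4e-14). Beside that shift, body wall muscle markers had a median of -0.43 (8 of 11 lower adjusted over the list alone, 5 with the replicate block; adjusted p = 4.8e-05). Neuron markers had a median of -0.36 (3 of 12 lower with the block; adjusted p = 0.033). Oocyte and embryo markers had a median of 0.23 (adjusted p = 4.8e-05) and germline markers 0.18 (4 of 13 higher adjusted over the list alone; adjusted p = 0.0023). In the same arrays genes of the collagen list had a median of -0.24 (14 of 82 lower with the block, camera adjusted p = 3.3e-07). CUB-like genes had -0.31 (1 of 12 lower, 4 adjusted over the list alone, 3 with the block; adjusted p = 0.0047), and C-type lectins -0.19 (2 of 75 lower, 9 adjusted over the list alone, 8 with the block; adjusted p = 0.0032). PMK-1 targets had -0.25 (2 of 10 lower, 4 adjusted over the list alone; adjusted p = 0.0086). Caenacins and nlp peptides (-0.29, adjusted p = 0.04), glucuronosyltransferases (-0.27, adjusted p = 0.029), glutathione S-transferases (-0.21, adjusted p = 0.035), intestine markers (-0.18, adjusted p = 0.02), fatty acid metabolism (-0.10, adjusted p = 0.024) and ribosomal proteins (-0.07, adjusted p = 0.0068, but 0.04 with quantile normalization, adjusted p = 0.03) completed the 15 lists called. These 6 lists, neuron markers and PMK-1 targets each lost the call without at least 1 of the 6 uninfected arrays (adjusted p = 0.055 to 0.85), and caenacins, glucuronosyltransferases and neuron markers with quantile normalization (adjusted p = 0.055 to 0.1). Caenacins, glucuronosyltransferases, neuron and intestine markers and ribosomal proteins lost it with the 3'/5' covariate (adjusted p = 0.062 to 0.36). Pharynx markers were called with the replicate block only (adjusted p = 0.043 against 0.085).

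In this comparison 11 probe sets (9 genes) were called lower and 0 higher by limma, of 1911 lower and 1594 higher at an unadjusted p under 0.05. The 3 values of the groups did not overlap for 29.1% of probe sets, where chance gives 10%. With the replicate block, 1106 were called, 817 lower and 289 higher, all 11 among them, and with the 3'/5' covariate 3. The count rested on single arrays: it was 687 without uninfected zip-2 RNAi array number 1, 208 without infected zip-2 RNAi array number 2, and 164 without uninfected control array number 1. It was 3, 4, 7, 4 and 7 without uninfected control array number 2 or 3, infected control array number 1, or uninfected zip-2 RNAi array number 2 or 3. Only zip-2 and ceeh-1 stayed called whichever array was left out. Without the 4 arrays at the extremes of the component that separates the RNAi groups 3 probe sets were called.

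**Figure D3:**
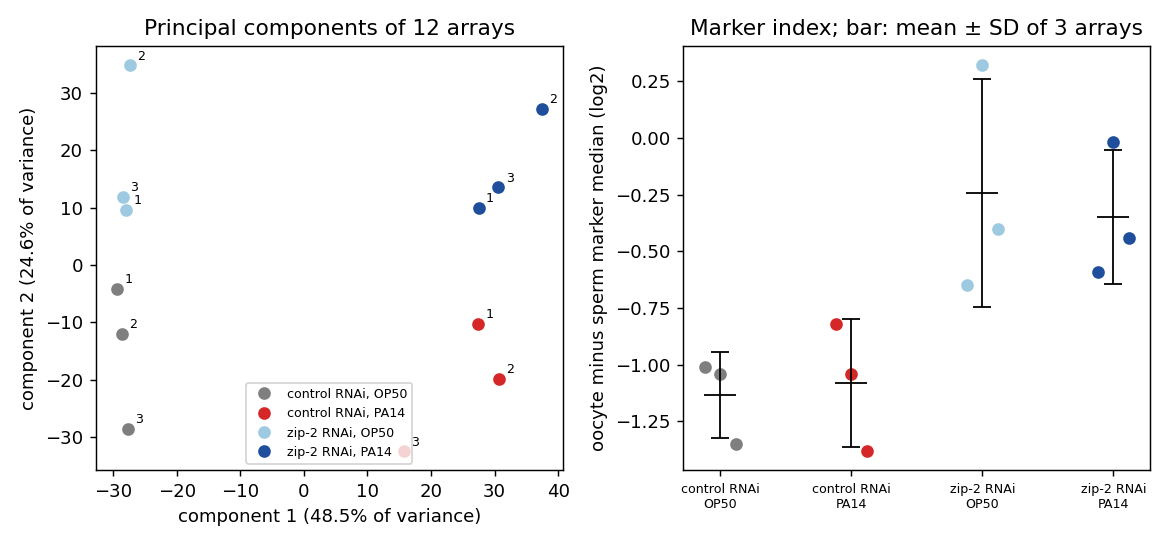
Principal components of the 12 arrays, with the replicate number beside each point, and the oocyte-minus-sperm marker index (log2) per array. Component 1 (48.5% of the variance) separates the bacteria and component 2 (24.6%) the RNAi groups, with zip-2 RNAi arrays number 2 (34.8 and 27.2) and control arrays number 3 (-28.5 and -32.4) farthest apart, and the index runs from -1.38 to 0.32.

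In infected animals more probe sets were called lower (456) than higher (68) with zip-2 RNAi. At an unadjusted p under 0.05 (limma) the balance was milder, with 1898 lower and 1343 higher. The P-glycoprotein transporter gene pgp-5 was at 735 ± 339 in control RNAi and at 8.33 ± 5.15 in zip-2 RNAi, with 1 Present call of 3 and a mean under the floor of detected signals. It was lower by at least 22.8-fold (adjusted p = 2.5e-05). Among the largest falls were irg-2 (at least 14.9-fold, 545 ± 368 against 4.1 ± 2.1), parg-2, a poly(ADP-ribose) glycohydrolase gene (at least 12.4-fold), Y58A7A.5 (at least 12.1-fold), C06B3.7 (-4.0 ± 0.40), irg-1 (-3.25 ± 0.52, adjusted p = 0.0084), F14F9.4 (-3.17 ± 0.33), C49G7.12 (at least 8.02-fold) and Y58A7A.3 (-3.03 ± 0.36). These falls and that of zip-2 stayed called whichever array was left out, while irg-1 was not called with an offset of 1 (adjusted p = 0.055). The other irg genes were not called: irg-3 (-0.09 ± 0.16), irg-4 (-0.60 ± 0.30), irg-5 (-0.85 ± 0.37), irg-6 (0.35 ± 0.30), irg-7 (-0.03 ± 0.12) and irg-8 (-0.14 ± 0.10). Fewer and smaller were the rises, such as Y37H2A.14 (1.43 ± 0.22), cpr-1, a cathepsin B-like protease gene of the intestine (1.11 ± 0.19), W03D2.6 (1.25 ± 0.21), C08E8.4 (1.32 ± 0.29), nspg-7.2 (1.47 ± 0.32) and T05A7.3 (at least 2.76-fold). The other 4 of the largest rises, clc-25 (at least 2.33-fold), fbxb-17 (at least 1.82-fold), T19C9.8 (at least 1.93-fold) and fbxb-41 (at least 1.92-fold), had no Present call in infected control animals. Of these 10 rises, only Y37H2A.14 and cpr-1 stayed called whichever array was left out.

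As a group, 6 of 45 glucuronosyltransferases, which conjugate toxins, were lower in infected zip-2 RNAi animals and 0 higher (18 and 0 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 2.7e-08, adjusted p = 0.25 with an estimated correlation). Among them were ugt-26 (-3.02 ± 0.25), ugt-29 (-2.88 ± 0.33), ugt-31 (-2.50 ± 0.26) and ugt-48 (-1.27 ± 0.17). The cytochrome P450 gene cyp-14A5 fell by 2.21 ± 0.25 (1 of 38 of that family, 1 adjusted over the list alone; adjusted p = 0.85). The 8 irg genes had 2 members lower (2 adjusted over the list alone; adjusted p = 0.0071 and, with an estimated correlation, adjusted p = 0.29). Of 6 cytosolic heat shock genes hsp-16.41 (-1.80 ± 0.25) and hsp-16.2 (-1.23 ± 0.18) fell (3 adjusted over the list alone; adjusted p = 0.02 and, with an estimated correlation, adjusted p = 0.33), but with all probe sets of the list the call ended (adjusted p = 0.2). Of 11 caenacins and nlp peptides 1 fell (9 adjusted over the list alone), with a median of -0.65 (adjusted p = 4.2e-05 and, with an estimated correlation, adjusted p = 0.35). Of 16 proteases 3 rose, cpr-1, cpr-4 (0.70 ± 0.14) and cpr-6 (0.49 ± 0.11) (3 adjusted over the list alone; adjusted p = 0.0071 and, with an estimated correlation, adjusted p = 0.29).

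The CUB-like genes and PMK-1 targets had 0 of 12 and 0 of 10 members called in infected animals, over all genes and adjusted over the list alone (limma), where at an unadjusted p under 0.05 there were 2 and 1 higher and 0 and 2 lower. Their medians were 0.08 and 0.03 (adjusted p = 0.57 and 0.75), and for PMK-1 targets the mean (-0.13) and the test pointed down. The oocyte-minus-sperm index was higher by 0.81 over both bacteria, while neuron (-0.14, adjusted p = 0.26) and intestine markers (0.04, adjusted p = 0.82) were not called in infected animals. Major sperm protein genes had a median of -0.50 (4 of 32 lower, 19 adjusted over the list alone; adjusted p = 1.4e-10 and, with an estimated correlation, adjusted p = 0.45) and body wall muscle markers of -0.45 (2 of 11 lower, 9 adjusted over the list alone; adjusted p = 2.2e-06 and, with an estimated correlation, adjusted p = 0.38). Oocyte and embryo markers had 0.22 (1 of 15 higher, 3 adjusted over the list alone; adjusted p = 5.8e-05 and, with an estimated correlation, adjusted p = 0.53). Beside that shift, genes of the collagen list had a median of -0.36. Of the 82, 13 were lower, or 33 adjusted over the list alone, which also calls 3 higher. The camera adjusted p was 2.6e-11 and, with an estimated correlation, 0.35. Glutathione S-transferases (-0.25, adjusted p = 0.0071), fatty acid metabolism (-0.12, 5 of 57 lower, 7 adjusted over the list alone, adjusted p = 0.016), ribosomal proteins (0.07, adjusted p = 0.02) and germline markers (0.13, adjusted p = 0.033) completed the 13 lists called, none of which was called with an estimated correlation (these 4 at adjusted p = 0.53, 0.54, 0.88 and 0.54). Of these 4, all but glutathione S-transferases lost the call without at least 1 of the 6 infected arrays (adjusted p = 0.06 to 0.53). With the 3'/5' covariate the proteases (adjusted p = 0.11), germline markers (adjusted p = 0.056) and ribosomal proteins (median 0, adjusted p = 0.68) lost it.

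In this comparison limma called 524 probe sets, 456 lower (385 genes, 171 probe sets 2-fold or more) and 68 higher (64 genes, 9 probe sets 2-fold or more). With the replicate block 1601 were called, 1204 lower and 397 higher, all 524 among them. With the 3'/5' covariate 52 were called, 50 of the 524 among them, and 19 of the genes named here. The fall of irg-1 was not (-2.62 ± 0.65, adjusted p = 0.11), while those of pgp-5 (adjusted p = 0.00075) and irg-2 (adjusted p = 0.013) were. The count rested on single arrays: it was 55 or 111 without infected zip-2 RNAi array number 2 or 3, 81 or 140 without infected control array number 3 or 2, and 161 without uninfected control array number 2. It was 291 or 955 without uninfected zip-2 RNAi array number 3 or 2. Of the 53 called genes named here, 19 stayed called whichever array was left out, and the other 34 lost the call without infected zip-2 RNAi array number 2. The 3 infected values did not overlap for 31.6% of probe sets, where chance gives 10%. Without the 4 arrays at the extremes of the component that separates the RNAi groups 132 probe sets were called. Across probe sets the effects of zip-2 RNAi in uninfected and infected animals, which share no array, had a Pearson correlation of 0.649 and a Spearman correlation of 0.563. In both, 5 probe sets were called lower, where independent lists would share 0.367. Same-numbered uninfected and infected arrays deviated together from their group means. Their correlations were 0.31, 0.35 and 0.17 in zip-2 RNAi and 0.37, 0.09 and 0.41 in control RNAi. The effects in uninfected and infected animals are thus not independent, and neither their correlation nor the 0.367 allows for this.

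**Figure D4:**
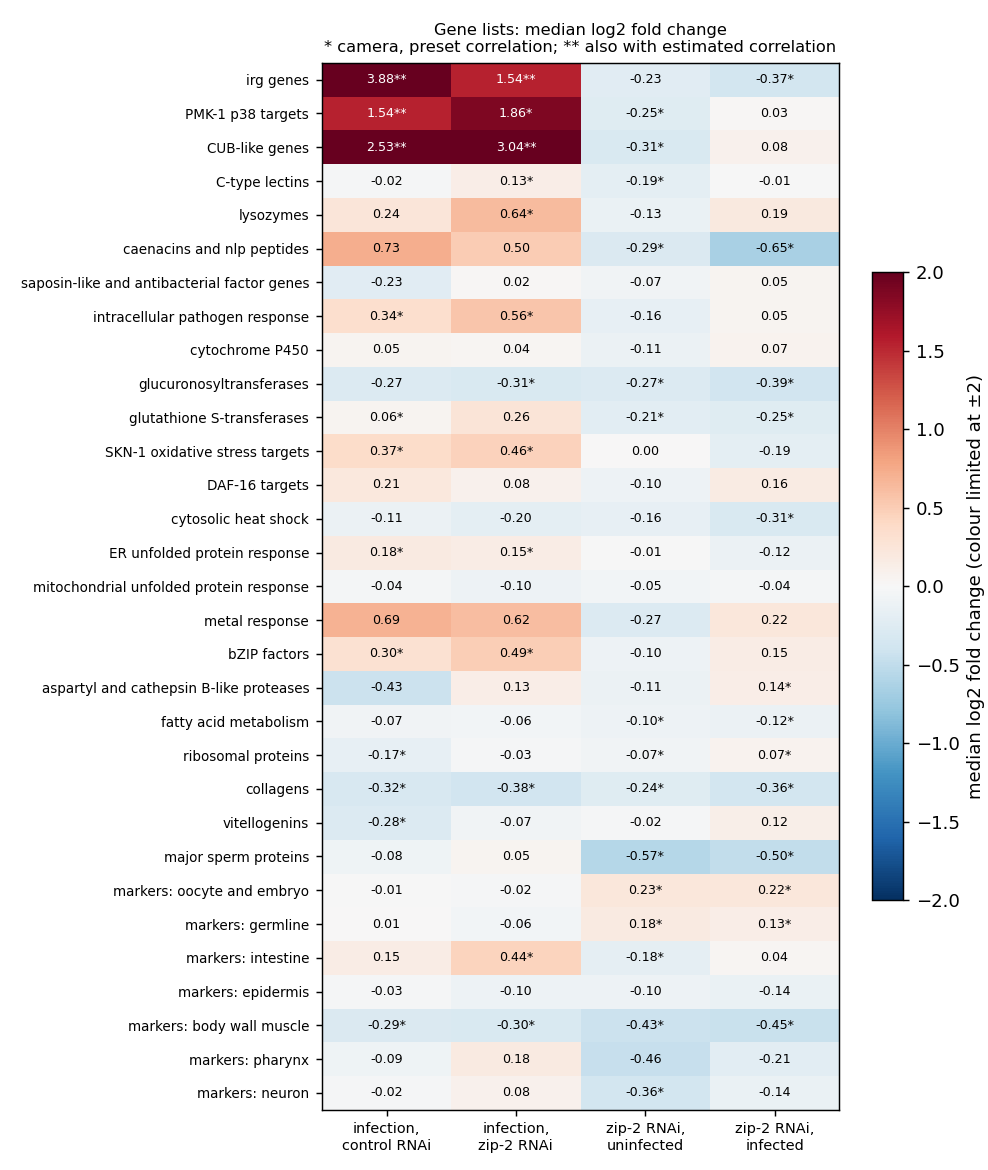
Median log2 change of 31 gene lists (y axis) in 4 comparisons (x axis), with * for lists called by camera at the preset correlation and ** for those also called with an estimated correlation. CUB-like genes (2.53 and 3.04) and irg genes (3.88 and 1.54) carry ** for infection in both RNAi groups, no list does for zip-2 RNAi, and the ribosomal medians of infection in control RNAi and of zip-2 RNAi in uninfected animals turn positive with quantile normalization.

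Tested directly, the infection effect differed between the RNAi groups for 9 genes, each lower in zip-2 RNAi. Of these, ugt-26 (-2.40 ± 0.35), F54B8.4 (-2.29 ± 0.32), ZK228.4 (-1.99 ± 0.21) and zip-2 (-1.03 ± 0.16) had Present calls in all 4 groups. The others were C06B3.7, irg-2, pgp-5, F14F9.4 and C49G7.12. Each of these 5 had no or 1 Present call in at least 2 groups, so the size of its difference rests on the offset (for C06B3.7 -5.71 with an offset of 1 and -2.98 with 64), and the 5 are not ranked. Adjusted p ran from 0.0034 for ZK228.4 to 0.044 for irg-2. With the replicate block 7 probe sets were called, 6 of them among these 9, and pgp-5 (adjusted p = 0.072), F14F9.4 (adjusted p = 0.064) and zip-2 (adjusted p = 0.064) lost the call. With the 3'/5' ratio of control transcripts as a covariate 0 were called (adjusted p = 0.52 to 1). ZK228.4 then had -1.74 ± 0.28, F54B8.4 -2.49 ± 0.45, ugt-26 -1.60 ± 0.38 and zip-2 -0.92 ± 0.23, with larger standard errors and, for all but F54B8.4, smaller differences. In control RNAi ugt-26 was at 527 ± 47.7 before and 1110 ± 434 after infection and ZK228.4 at 964 ± 161 and 1160 ± 250, whereas in zip-2 RNAi they were at 337 ± 48.5 and 116 ± 23.7 and at 759 ± 64.7 and 217 ± 21.9. For irg-1 the difference was -2.58 ± 0.74 and not called (adjusted p = 0.55), so that a difference as large as that of ugt-26 is left open there. For irg-3 it was 0.06 ± 0.22.

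Of the gene lists, the aspartyl and cathepsin B-like proteases had a higher infection effect in zip-2 RNAi (median 0.23, 0 of 16 called by limma over all genes, 5 higher adjusted over the list alone and 7 at an unadjusted p under 0.05; camera adjusted p = 8.1e-08, adjusted p = 0.025 with an estimated correlation). With the replicate block the call was lost at an estimated correlation (adjusted p = 0.17). CUB-like genes (0.38, 4 of 12 higher adjusted over the list alone; adjusted p = 2.2e-05) and glucuronosyltransferases (-0.13, 1 of 45 lower, 8 adjusted over the list alone; adjusted p = 2.2e-05) were called too, both at an adjusted p = 0.19 with an estimated correlation. Intestine markers (0.26, adjusted p = 3e-04), PMK-1 targets (0.34, adjusted p = 0.0079), C-type lectins (0.15, adjusted p = 0.0079), lysozymes (0.40, adjusted p = 0.0079), vitellogenins (0.21, adjusted p = 0.027) and ribosomal proteins (0.14, adjusted p = 6.7e-10) had positive medians too. None of these 6 was called with an estimated correlation (adjusted p = 0.19, 0.45, 0.61, 0.36, 0.61 and 0.61). The vitellogenin call ended with the replicate block (adjusted p = 0.056). The ribosomal call ended with quantile normalization (median 0.01, adjusted p = 0.69). With the 3'/5' covariate intestine markers, PMK-1 targets, vitellogenins, ribosomal proteins and heat shock genes lost it (adjusted p = 0.17 to 0.73). Caenacins and nlp peptides (-0.27, adjusted p = 0.013) and cytosolic heat shock genes (-0.07, adjusted p = 0.023) had negative medians and were not called with an estimated correlation either (adjusted p = 0.61 and 0.27). Of these 11 of 31 lists, only the proteases were called with an estimated correlation, and none with the replicate block besides.

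Limma called 0 of 13684 probe sets with a higher infection effect in zip-2 RNAi and 9 with a lower one, of 438 and 273 at an unadjusted p under 0.05. Only ZK228.4 stayed called whichever array was left out. The count was 27 without infected control array number 3. It was 6 and 3 without the zip-2 RNAi arrays number 2, uninfected and infected. It was 2 without uninfected control array number 3 or either infected array number 1, and 1 without any other array. Without the detection filter or with an offset of 1 it was 1, with eBayes without trend 2, and without the 4 arrays at the extremes of the component that separates the RNAi groups 18.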

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

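The tests of the genes beside zip-2, of infected control array number 3 and of splits of the residuals were chosen after the values were seen, and those of the tissue markers and of other splits of the samples were planned.

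For 9 genes the infection effect (log2) differed between zip-2 RNAi and control RNAi by the test of the difference itself. The difference was -4.25 for C06B3.7, -4.11 for irg-2, -3.32 for pgp-5, -2.96 for F14F9.4, -2.75 for C49G7.12, -2.40 for ugt-26, -2.29 for F54B8.4, -1.99 for ZK228.4 and -1.03 for zip-2. Each was negative, that is, the effect in zip-2 RNAi lay below that in control RNAi. For C06B3.7, irg-2, pgp-5, F14F9.4 and C49G7.12 these are fitted values of probe sets with no or 1 Present call in at least 2 groups. Their size and order rest on the offset of 16, and only the direction is read from them. With the mean 3'/5' ratio of control transcripts as a covariate 0 of them were called, and they ran from -3.43 to -0.92. That ratio rose with infection in zip-2 RNAi by 0.19 ± 0.04 and in control RNAi by 0.06 ± 0.04, so a part of RNA quality or labelling in these differences stays open. For zip-2 itself the difference is that of the RNAi target, whose signal was at 288 after infection in zip-2 RNAi against 2840 in control RNAi.

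Whether other splits of the samples give as many calls was tested. For the difference of infection effects, 11 of 100 drawn splits (of 200), the real one included, gave 9 calls or more, and the highest of the others gave 89. This decides nothing on chance, because those splits all kept the infected arrays of each RNAi group together and with them the effect of zip-2 RNAi in infected animals. The 88 drawn splits that mixed the infected arrays gave 0. With the effects of RNAi and bacterium removed and the residuals exchanged within each bacterium, 3 of the same 100 splits, the real one included, gave 9 calls or more. The highest other split of the residuals gave 312, which points to a structure of the samples that the groups do not describe. For the other comparisons each made 10 splits of 6 arrays, too few for a share under 0.05. The real split, 1 of the 10 in each, gave 1758, 2167, 11 and 524 calls and the highest other split 0 each time. These numbers are for infection in control RNAi, infection in zip-2 RNAi, and zip-2 RNAi in uninfected and infected animals.

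The zip-2 RNAi arrays had higher oocyte and germline marker signal and lower sperm and muscle marker signal than the control RNAi arrays on both bacteria. The oocyte-minus-sperm index differed by 0.81 (SE 0.19). This SE, like those of the other gaps over both bacteria, takes the 12 arrays as independent. Uninfected and infected arrays with the same RNAi and number had similar indices. They were -1.35 and -1.38 for control RNAi number 3, and 0.32 and -0.02 for zip-2 RNAi number 2. These SEs may therefore be too small. A scale factor per array cancels in this index, a difference of 2 medians within 1 array, so the index cannot test such scaling. A difference in the distribution of signal between arrays is argued against as the cause of the gap, because quantile normalization left 0.78 (SE 0.18). RNA quality or labelling as the whole cause is argued against as well. With the mean 3'/5' ratio of 4 control transcripts as a covariate the gap was 0.82 (SE 0.2), and the ratio was lower in zip-2 RNAi in uninfected animals (-0.05, SE 0.04) and higher in infected ones (0.08, SE 0.04). The index was higher in both (0.89 and 0.73, SE 0.28 each). A difference in stage or germline make-up between the cultures stays open. Within groups, the oocyte and sperm marker medians of the 12 arrays had a Pearson correlation of -0.41 (permutation p = 0.21) and a Spearman correlation of -0.48 (permutation p = 0.16). Without the 2 arrays farthest from the median, r was -0.40. A slightly different age of the cultures at harvest is a candidate explanation, and so is an effect of zip-2 RNAi on growth or on the germ line. These cannot be told apart here, since an age difference was not measured and would coincide with the RNAi groups.

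The gene ceeh-1, next to zip-2 on chromosome 3, was lower in zip-2 RNAi by at least 6.07-fold in uninfected animals and with a log2 change of -2.16 ± 0.27 in infected ones (adjusted p = 0.0013). K02F3.9, on the other side of zip-2, had -0.68 ± 0.12 (adjusted p = 0.063) and -0.74 ± 0.12 (adjusted p = 0.011). Silencing that spreads to neighbouring genes could lower them. The 6 tested neighbours other than ceeh-1 had a median of -0.04, at percentile 34 of 10357 windows (SD of windows 0.15), which decides nothing. Of the 6, far-8 had -0.94 ± 0.43 and -0.71 ± 0.43 (adjusted p = 0.19 and 0.33), and the 4 besides it and K02F3.9 ran from -0.13 to 0.16. Loss of ZIP-2 as an activator of ceeh-1 could do so too. The infection effect on ceeh-1 differed between the RNAi groups by 0.55 ± 0.38, which excludes neither. An RNAi clone that also holds sequence of ceeh-1 is a further possibility, and the sequence of the clone was not analysed here, so its overlap with the zip-2 probes of the array is not known either.

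Infected control array number 3 had lower signal of genes classed as zip-2-dependent than the other infected control arrays, for example 130.8 for irg-2 against 671.6 and 833.8. Animals or RNA of zip-2 RNAi mixed into that sample are argued against. To lower these 32 genes by 69.6% of their difference, the mixture would need a zip-2 signal of 1118, and the array had 2473, where the SD of the group is 507. A weaker infection response of that culture may be a part of the cause, as a hypothesis from the same data. The array kept 75.5% (71 to 83.3%) of the median log2 rise of 256 infection-induced genes classed as zip-2-independent (1.18 against 1.57 in the other numbers). Of 33 classed as zip-2-dependent it kept 68.4% (53.1 to 96.5%, 1.61 against 2.36), a gap of 7.1 percentage points. The classes do not show that a gene is independent of zip-2. These are shares of log2 rises, while the 69.6% above is a share of linear signal, so the percentages cannot be set side by side. For 22 genes called lower in infected zip-2 RNAi it was 62.1% (45.3 to 74.7%), a gap of 13.4 percentage points. The response was not weaker in every gene. Of the 256 genes, 155 (60.5%) had their lowest infected control signal on this array and 53 their highest, and gst-38 was at 7529.1 against 6799.5 and 7105.5. Of the 33 dependent genes 28 (84.8%) were lowest on it, and of the 22 called lower 21 (95.5%). The low signal thus fell more often on dependent genes. With number 1 or 2 left out instead, the gap was 13.9 or -20 percentage points, so the gap of 7.1 decides little. Uninfected control array number 3 was the highest of its group for 155 of the 256, so a part of the smaller rise lies in that array.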

How the results depend on the processing

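The replicate block with only the groups compared, the fits without 4 arrays at the extremes of component 2, the fit with the mean 3'/5' ratio of control transcripts as a covariate, and the replicate block with estimated correlation were chosen after the data were seen.

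Under every alternative run, the count for infection in control RNAi stayed within 1.5 times and the fall of zip-2 stayed called. The count for infection in zip-2 RNAi did so too, except for 454 with the 3'/5' covariate. The balance of these counts did not stay: control RNAi had 935 higher and 823 lower, but 828 and 1010 with centring on the 75th percentile, and zip-2 RNAi had 1178 and 989, but 1113 and 1141 with quantile normalization. The median difference of induced genes was not computed in those fits or with the 3'/5' covariate. Elsewhere it stayed positive (0.01 with array weights to 0.13), though with genes chosen without replicate number 1 and measured in it, it was -0.08. Leaving out 1 array gave 1205 to 1873 and 1621 to 2228 calls, a zip-2 change of -2.23 to -2.13 in uninfected and -3.31 to -3.08 in infected animals, and a median difference of induced genes of 0.04 to 0.13.

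The count for zip-2 RNAi in uninfected animals (11) was 1106 with the replicate block, 287 with that block and only the groups compared, 528 with array weights, 7 without a detection filter, 6 with eBayes without trend, 4 with only the groups compared, 3 without the 4 extreme arrays and 3 with the 3'/5' covariate. That for infected animals (524) was 1601, 1105, 964, 138 and 126 in the first 5 of these settings, 132 without the extreme arrays and 52 with the covariate. That for the difference of infection effects (9) was 18 with array weights and 18 without the extreme arrays, 2 with eBayes without trend, 1 without a filter or with an offset of 1, and 0 with the covariate. Leaving out 1 array gave 3 to 687, 55 to 955 and 1 to 27. The covariate raised the standard errors, by a median of 1.16 times for zip-2 RNAi in uninfected animals to 2.24 times for infection in zip-2 RNAi. For the other settings the cause was not tested.

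Of the list tests, 3, 2, 0, 0 and 1 stayed called with an estimated correlation, in the order of the comparisons (12, 13, 15, 13 and 11 at the preset one), and 2, 2, 0, 0 and 0 with the block besides. With fry 0 were called for zip-2 RNAi in uninfected animals, 6 in infected ones and 1 for the difference; fry does not compare a list with other genes. Leaving out 1 array gave 12 to 13, 9 to 17, 10 to 15, 11 to 13 and 8 to 13.

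Quantile normalization reversed the ribosomal medians of infection in control RNAi (0.01) and of zip-2 RNAi in uninfected animals (0.04), the 3'/5' covariate that of zip-2 RNAi in infected animals (0), and quantile normalization, among genes not called, irg-5 for zip-2 RNAi in uninfected animals (0.03) and the differences of irg-3 and irg-6 (0 each). Array weights reversed irg-5 (0.32) and irg-6 (-0.09) in uninfected and irg-3 (0.05) and irg-7 (0.01) in infected animals. Leaving out 1 array gave, for zip-2 RNAi in uninfected animals, -0.49 to 0.25 for irg-4, -0.43 to 0.35 for irg-5 and -0.09 to 0.40 for irg-6. In infected animals it gave -0.25 to 0.08 for irg-3 and -0.10 to 0.06 for irg-7, and for the difference -0.09 to 0.23 for irg-3 and -0.05 to 0.44 for irg-6. The cause was not tested.

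Of 6357 values of 290 gene results, the 3'/5' covariate not included, 5847 kept direction and side of the threshold, 477 lost the call, 11 gained it and 22 reversed; of 1536 values of 64 list results it was 1288, 245, 0 and 3. The other deposited table was not run as an alternative, since its signal columns were not used here. Genes at or below the lowest signal of detected probe sets (8 to 18.7) allow bounds only.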

Other observations

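All tests of gene families in this part were chosen after the data were seen.

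Families of genes that share a symbol prefix and have 8 or more tested members (147 families) were tested with camera in each comparison. With an estimated correlation the calls given here were lost, so they describe only the direction of medians. Medians are log2 changes, with the adjusted p at the preset correlation.

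With infection in control RNAi, 5 of 10 prx genes of the peroxisome were called higher (median 0.43, adjusted p = 0.0012), as were 4 of 12 atg genes of autophagy (0.30, adjusted p = 0.0073), 5 of 11 galectin genes (lec, 0.46, adjusted p = 0.022) and 21 of 88 fbxa F-box genes, with 2 lower (0.12, adjusted p = 0.0073). Of 34 mrpl genes 3 were called lower (-0.14, adjusted p = 0.00087), of 24 mrps genes 5 (-0.18, adjusted p = 0.0012) and of 12 cox genes 2 (-0.17, adjusted p = 0.022, but -0.03 with quantile normalization). Of 8 elo genes, which encode fatty acid elongases, 4 were called lower (-0.56, adjusted p = 0.00067). In zip-2 RNAi, 28 of 127 nuclear hormone receptor genes (nhr) were called higher with infection and 1 lower (0.22, adjusted p = 0.00024).

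For zip-2 RNAi against control RNAi, the 18 spe genes had a median of -0.61 in uninfected animals (adjusted p = 0.00038) and -0.64 in infected ones (adjusted p = 0.00035), and the 8 ssp genes -0.80 (adjusted p = 3.1e-05) and -0.73 (adjusted p = 4.9e-05). In uninfected animals the 8 mcm genes had a median of 0.26 (adjusted p = 0.00079) and the 26 npp genes of 0.17 (adjusted p = 2.7e-05), beside 0.23 for oocyte and embryo markers and 0.18 for germline markers. The 33 transthyretin-like genes (ttr) had -0.18 (adjusted p = 0.0026) and -0.24 (adjusted p = 0.00011).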
